A study of Mus musculus with 6 samples.

How the data were processed

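Total RNA from jejunum, the middle part of the small intestine, was sequenced from germ-free C57BL/6 mice. Germ-free mice carry no microbes. Of 6 libraries, 3 came from conditioned mice, which had received E. coli HA107 by gavage at 1e10 CFU on each of 4 occasions, every other day, 2 weeks before sampling. HA107 is a strain that cannot persist in the gut, so that the mice return to the germ-free state. The other 3 libraries came from unconditioned mice gavaged with buffer. Per the labels' protocols, ribosomal RNA was depleted and libraries were made with an Illumina TruSeq kit, for which the labels name both an RNA v2 and a stranded mRNA version, and sequenced on an Illumina HiSeq instrument. Groups and replicate numbers were read from the sample titles.

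Per the submitters' processing notes, the tools were FastQC 0.11.2, Trimmomatic 0.33, TopHat2 2.0.13, HTSeq 0.6.1 and DESeq2 (version not given), with the genome build mm10. The strand setting of the counting and the gene annotation release are not given in the sources used here, so reads of overlapping genes on opposite strands may not have been told apart. The authors deposited a table of raw counts per Ensembl gene for 47069 genes and a second table with 37682 genes. Per the file headers, the second table holds the authors' own comparison, with log2 fold changes, their standard error and test statistic (a score), p-values and adjusted p-values, and the mean over samples of the authors' normalized signal. The per-sample columns of that deposited table are raw counts and not normalized values: they were identical to the count table for all 36922 shared genes. The 760 genes found only there had 0 counts, and 10147 genes of the count table were not listed there. These took 11.3% to 14.3% of the counts of a library. The count table was therefore used for all tests, and 0 columns of per-sample values belonged to no sample here.

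Gene symbols were matched by Ensembl ID to GENCODE mouse release M21 for 46488 genes. Another 301 took the symbol of the authors' deposited table, and 280 kept their ID. Coordinates are from the same release, on the same build (mm10). Library totals ran from 31086757 to 38207890 counts. A count of 0 (a limit of 3 counts) allows up to between 0.0785 and 0.0965 CPM per library. Such floors and the 95% intervals of count ratios cover counting error only.

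The comparison was conditioned against unconditioned, with edgeR 4.0.16 in R 4.3.3: default expression filter (20086 genes kept), TMM scaling, robust quasi-likelihood test, and Benjamini-Hochberg adjustment with a threshold of 0.05. Log2 fold changes are conditioned over unconditioned and are given with their standard error (SE), taken as the absolute log2 fold change divided by the root of the F statistic. CPM values use the TMM-scaled library size. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these samples. An exact permutation test of 3 against 3 samples could not fall below p = 0.1, so no such test was used.

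Gene lists were fixed before the data were examined: 37 lists of response genes, cell type markers and signs of tissue handling or RNA quality. Lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, adjusted over 36 lists. They were tested again with an estimated correlation and with fry. The calls of list members were also adjusted over the list alone. The rule for naming genes was fixed at the same time. It takes up to 10 genes per direction with the largest fold change among those that passed with groups that did not overlap, immunoglobulin and T cell receptor segments, Gm and Rik symbols and genes without a symbol not ranked. Where under 5 passed in a direction, it takes the 5 smallest p-values as values that did not pass. It adds the 2 members of each list with the smallest unadjusted p, always Igha, Jchain, Igkc, Pigr, Reg3b, Reg3g, Saa1, Ighm and Mzb1, and up to 3 segments that passed per direction. Saa1 had too few counts to be tested, and some members that the rule names are not reported here.

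Alternatives fixed at the start were DESeq2 size factors, upper-quartile scaling or library sizes alone in edgeR, no filter beyond 1 count, a filter of CPM at least 1 in 3 samples, DESeq2 1.42.0, limma-voom, the replicate number as a block, immunoglobulin or mitochondrial genome genes left out, each library left out in turn, and stricter thresholds (1.5-fold, or an adjusted p of 0.01). A per-library offset on transcript length, and the libraries left out in turn from the DESeq2 fit, were added after seeing the data. In each fit with a library left out the expression filter was run again, which kept 20425 to 20652 genes. The tested members of a list may therefore differ between these fits and the main one, and a changed median need not come from the library left out.

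The scripts were tested on simulated data: counts for 20086 genes with the means, library sizes and dispersions of this comparison, and 200 genes changed. The changed genes were drawn from those with a mean above 1 CPM. Of the genes changed 1.5-fold, 2-fold and 4-fold, edgeR recovered 23.9%, 59.7% and 97%, and DESeq2 35.8%, 74.6% and 97%. With 200 genes changed the adjusted threshold is easier to pass than in the data, where edgeR called 3 genes. These shares therefore do not carry over: in the data Ighv1-81, 27.9-fold apart, missed (edgeR adjusted p = 0.0826). Of 142 edgeR calls 22 were false, and of 190 DESeq2 calls 52 were false. With no gene changed, edgeR called 2 genes and DESeq2 17. In the simulation of lists, camera called the list of 20 genes raised 1.5-fold and 0 of 35 unchanged lists, whose members were simulated as independent.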

Results

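The jejunal transcriptome of HA107-conditioned and unconditioned germ-free mice was compared, with 3 libraries each, to ask what a passing exposure to a bacterium leaves in the small intestine. The conditioned libraries held 37473324, 38207890 and 31086757 counts for replicates 1 to 3, and the unconditioned ones 32835749, 35862726 and 33378202. Between 26648 and 27301 genes had at least 1 count in a library. The non-coding RNA 7SK took 4.58% to 6.96% of the counts and the mitochondrial ribosomal RNAs 3.73% to 6.76%.

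BC035947, an uncharacterised protein-coding gene, was present in the conditioned and nearly absent from the unconditioned jejunum. Its counts were 140, 268 and 170 in the conditioned libraries and 1 in each unconditioned library. Per1, a repressor of the circadian clock that also responds to hormones, rose 1.79-fold. Igkv4-70, a variable segment of the immunoglobulin kappa light chain, rose 6.16-fold from a low level. These 3 genes were the edgeR calls among 20086 genes, and 0 genes were lower. Unadjusted p-values under 0.05 were reached by 1397 genes (918 higher, 479 lower), where 1004 would be reached by chance. DESeq2 called 169 genes on the same counts.

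BC035947 (ENSMUSG00000090486) lies on the minus strand of chromosome 1 from 78497026 to 78512158 (mm10). It stood at 5.64 ± 1.79 CPM (SD, n = 3) in conditioned and 0.0284 ± 0.000764 CPM (SD, n = 3) in unconditioned libraries. The second SD reflects scaled library size alone, since each unconditioned library had 1 count, and it does not measure precision. With 578 counts against 3, the ratio was 199, with an exact 95% counting interval of 67.6 to 965. The fitted log2 fold change was 7.46 ± 0.42 (edgeR adjusted p = 0.000482), and the gene passed with each of the 6 libraries left out. At its 5' end it overlaps Mogat1, a lipid synthesis gene on the plus strand from 78510991 to 78538173, and 200 exon bases are shared while 3110 are its own. The strand setting is not given in the sources used here, so reads in the shared bases are uncertain.

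Per1 (ENSMUSG00000020893; chromosome 11, plus strand, 69095217 to 69109960) stood at 80.1 ± 5.88 CPM (SD, n = 3) in conditioned and 44.7 ± 0.993 CPM (SD, n = 3) in unconditioned libraries, a log2 fold change of 0.84 ± 0.09 (edgeR adjusted p = 0.0489). Igkv4-70 (ENSMUSG00000076547; chromosome 6, minus strand, 69267888 to 69268443) stood at 1.41 ± 0.242 and 0.226 ± 0.0232 CPM (SD, n = 3 each), a log2 fold change of 2.62 ± 0.29 (edgeR adjusted p = 0.0489). Variable segments resemble each other, so its reads are uncertain. Both calls lay close to the threshold. Without conditioned replicate 2, 3 or unconditioned replicate 1, 2 or 3, Per1 had an adjusted p of 0.0546, 0.0979, 0.127, 0.286 and 0.236. Igkv4-70 missed without conditioned replicate 1 or 3 or unconditioned replicate 1, 2 or 3, at 0.0624, 0.0979, 0.127, 0.286 and 0.236.

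**Figure D1:**
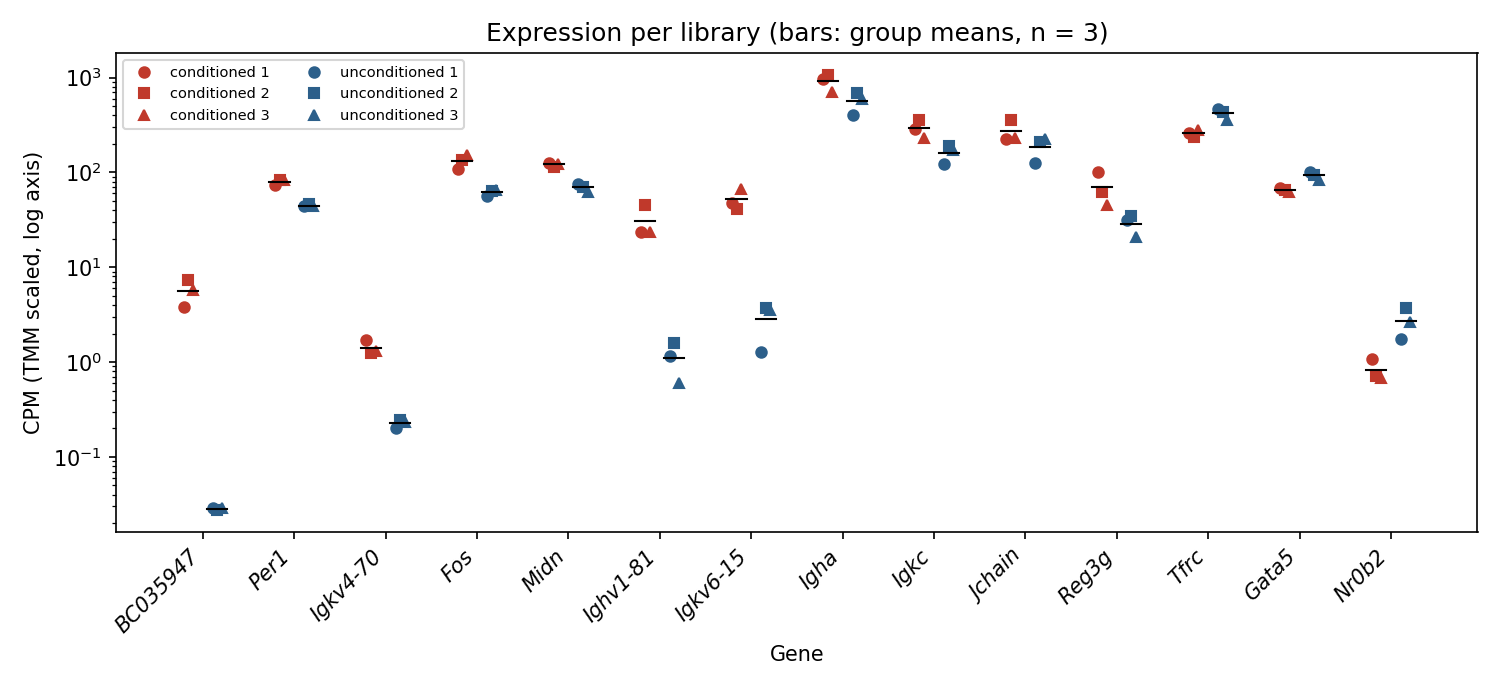
Expression per library of genes named in the text, in TMM-scaled CPM on a log axis; red symbols are the 3 conditioned and blue symbols the 3 unconditioned libraries, and bars are group means (n = 3). BC035947 sits between 3.82 and 7.39 CPM in conditioned libraries and at 0.0275 to 0.0288 CPM in unconditioned ones; of the genes shown, BC035947, Per1 and Igkv4-70 passed the edgeR test.

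The genes next in rank did not pass. Fos, a subunit of the AP-1 transcription factor, stood at 132 ± 22.3 CPM in conditioned and 61.7 ± 5.11 CPM in unconditioned libraries (SD, n = 3 each; log2 fold change 1.09 ± 0.13, edgeR adjusted p = 0.0744). Midn, which carries nuclear proteins of immediate early genes to the proteasome, had 0.81 ± 0.10 (edgeR adjusted p = 0.0744). Of genes with lower values, Tfrc, the transferrin receptor for iron uptake, stood at 260 ± 22.6 against 422 ± 56.1 CPM (SD, n = 3 each; -0.70 ± 0.13, edgeR adjusted p = 0.205). The transcription factor Gata5 had a log2 fold change of -0.51 ± 0.10 and Nr0b2, a nuclear receptor that represses bile acid synthesis, -1.69 ± 0.33. Tmem238l had -0.56 ± 0.11 and Gm13130 -1.35 ± 0.26. In these 5 genes all conditioned values lay below all unconditioned ones, which their choice by smallest p-value favours, so this adds no support. Groups did not overlap in 13.3% of tested genes, where chance gives 10%.

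By DESeq2, 159 genes were higher and 10 lower. Without conditioned replicate 1, DESeq2 gave 347 higher and 106 lower. The rule for large fold changes was applied to these calls after the values were seen. Besides BC035947, it gave the histone genes Hist1h2ad (log2 fold change 3.28 ± 0.69), Hist1h2ak (2.94 ± 0.83), Hist1h2ac (2.90 ± 0.67) and Hist2h2ac (2.68 ± 0.48). In conditioned replicate 2 these stood at 0.414, 1.52, 0.496 and 1.60 CPM. The other conditioned libraries had at least 1.24, 8.26, 1.44 and 5.91 CPM, and the unconditioned ones at most 0.144, 1.38, 0.374 and 1.09 CPM. The rule also gave the calcium channel Cacna1i (3.12 ± 0.80; 3.34 CPM in conditioned replicate 2 against 0.491 and 0.873 CPM in the other conditioned libraries), the immunoglobulin constant gene Ighg2b (2.69 ± 0.69; 13.7 CPM in conditioned replicate 2 against 4.50 and 4.46 CPM), the detoxification enzymes Cyp1a1 (2.53 ± 0.61) and Cyp3a44 (1.96 ± 0.53) and the carotene-cleaving enzyme Bco1 (1.98 ± 0.32). The genes that fell by DESeq2 with the largest changes were Nr0b2 (-1.69 ± 0.38), Lypd1 (-1.01 ± 0.27), Dpysl5 (-0.74 ± 0.21), Tfrc (-0.69 ± 0.14), Cyp2j9 (-0.55 ± 0.16), Tmem238l (-0.55 ± 0.13), Gata5 (-0.51 ± 0.12) and Hjurp (-0.45 ± 0.11).

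At an adjusted p below 0.05, the authors' deposited table gave 118 genes as higher and 5 as lower in conditioned mice. Of these, 121 passed the expression filter here. All 121 were also called by DESeq2 here, and all 121 had the same sign in edgeR with an unadjusted p under 0.05. The counts were the same, so this is no independent check. Of the DESeq2 calls here, 22 genes were not listed in the authors' deposited table, 8 of them histone genes. By the same rule, applied after the values were seen, the authors' deposited table gave the largest log2 fold changes to BC035947 (2.55), Cebpd (1.22), Dusp1 (1.14), Pmaip1 (1.14), Bco1 (1.13), Foxq1 (1.02), Hist2h2ac (0.997), Defa26 (0.96), Iglc2 (0.94) and Fos (0.94). Its 5 lower genes were Nr0b2 (-0.84), Lypd1 (-0.66), Tfrc (-0.61), Tmem238l (-0.49) and Gata5 (-0.46). The segments with the largest values in the authors' deposited table were Ighv1-81 (2.69), Ighv1-53 (1.45) and Igkv6-15 (1.30). Its log2 fold changes were smaller in size than those found here on identical counts. For BC035947, Nr0b2 and Ighv1-81, DESeq2 here gave 7.64, -1.69 and 4.81. Sizes and ranks by size are therefore not comparable between the deposited values and those here. Across 17841 genes, which are not independent replicates, fold changes of the authors' deposited table and of edgeR had a Pearson r of 0.814 and a Spearman rho of 0.979.

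Of 141 immunoglobulin variable segments tested, 108 had higher and 33 lower values in conditioned mice, and the 23 segments called by DESeq2 were all higher. The IgA plasma cell list had 18 of 20 members higher and a median log2 fold change of 0.56 (camera adjusted p = 2.75e-08; adjusted p = 0.353 with an estimated correlation). Igha, the constant region of IgA, stood at 913 ± 186 CPM in conditioned and 559 ± 141 CPM in unconditioned libraries (SD, n = 3 each), 1.63-fold apart. Its groups did not overlap, but it did not pass over all genes (0.71 ± 0.22, edgeR adjusted p = 0.577).

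Over all genes 0 of the 20 plasma cell list members passed by edgeR (6 at an unadjusted p under 0.05, 2 by DESeq2), and adjusted over the list alone 2 did, the light chain genes Iglc2 (1.82 ± 0.38) and Igkc (0.85 ± 0.20). Jchain, which joins IgA into dimers, had 0.54 ± 0.26, and Mzb1, a chaperone of antibody assembly, 0.71 ± 0.40. Pigr, the receptor that carries IgA into the lumen, had 0.23 ± 0.31. Without conditioned replicate 2, the highest library for this list, its median was 0.37.

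Heavy chain variable segments rose as a list (median log2 fold change 1.13, 56 of 71 higher, camera adjusted p = 3.9e-12; adjusted p = 0.353 with an estimated correlation). Of them 0 passed over all genes by edgeR (25 at an unadjusted p under 0.05, 14 by DESeq2) and 13 adjusted over the list alone, all higher. Ighv1-81 had 31.1 ± 12.6 against 1.11 ± 0.482 CPM (SD, n = 3 each) and a log2 fold change of 4.80 ± 0.44. Ighv1-53 had a log2 fold change of 2.13 ± 0.28. Light chain variable segments rose as a list too (median 1.09, 52 of 70 higher, camera adjusted p = 1.76e-08; adjusted p = 0.353 with an estimated correlation). Of them 1 passed over all genes by edgeR, Igkv4-70, and 9 adjusted over the list alone, all higher. At an unadjusted p under 0.05, 17 light chain segments were higher and 3 lower, and DESeq2 called 9. Igkv6-15 had 4.19 ± 0.43. Ighv1-81 made up 4.87%, 7.24% and 5.75% of heavy variable counts in conditioned and 0.712%, 0.688% and 0.23% in unconditioned libraries. Igkv6-15 made up 11.6%, 6.85% and 20.3% of kappa variable counts in conditioned and 0.765%, 1.76% and 1.53% in unconditioned libraries. With libraries left out, the median of the heavy chain list ran from 0.71 without conditioned replicate 1 to 1.48 without unconditioned replicate 3. Each of these medians is over the members that passed the filter in that fit, so the members may differ as well as the libraries.

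**Figure D2:**
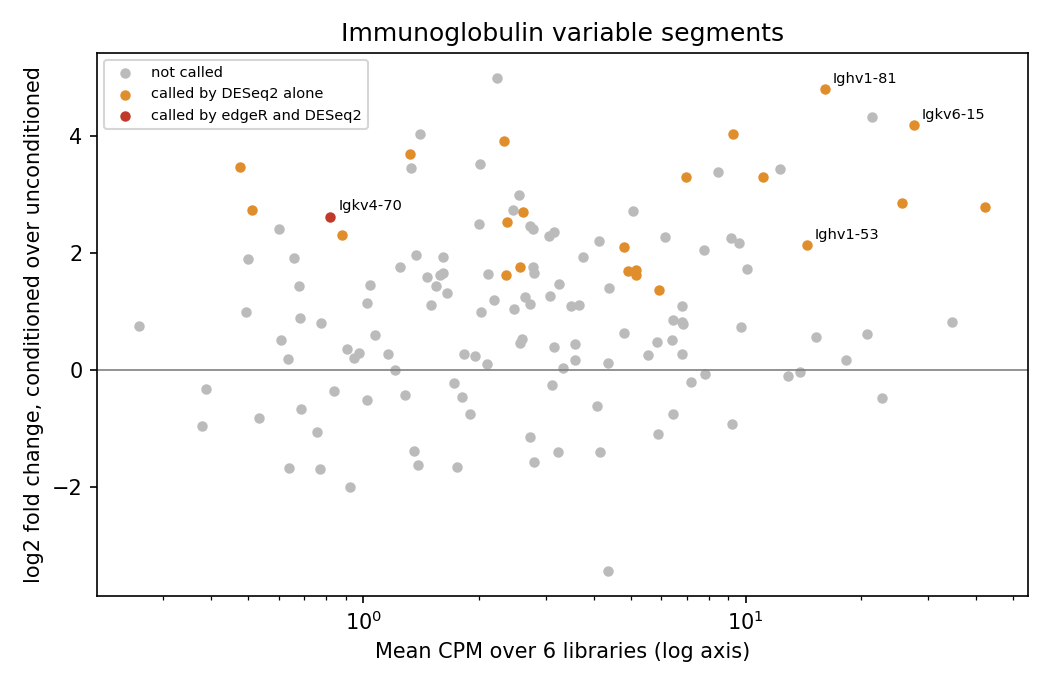
Log2 fold change (conditioned over unconditioned) of the 141 immunoglobulin variable segments tested against their mean CPM over 6 libraries on a log axis; each point is a segment. The 23 segments called by DESeq2 lie above 0, and Igkv4-70 alone was also called by edgeR.

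B cell and germinal centre genes had 18 of 19 members higher (median log2 fold change 1.81, camera adjusted p = 5.04e-07; adjusted p = 0.541 with an estimated correlation). This list stood apart in conditioned replicate 2, where the mean log2 CPM of its members lay 2.36 above the mean of the 6 libraries, against -0.83 to 0.38 in the other libraries. Without that library the median was 0.50. Fcrla had 1.86 ± 0.67, Cxcr5 2.59 ± 1.08 and Ighm, the constant region of IgM, 1.78 ± 0.83. No member passed, over all genes or adjusted over the list alone (0 of 19 by edgeR, 0 by DESeq2 and 1 at an unadjusted p under 0.05).

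All 34 tested Paneth cell genes were higher (median log2 fold change 1.17, camera adjusted p = 3.25e-13; adjusted p = 0.493 with an estimated correlation), with 0 calls by edgeR over all genes or adjusted over the list alone, 14 at an unadjusted p under 0.05 and 4 by DESeq2. The alpha-defensin Defa30 stood at 2267 ± 639 against 970 ± 334 CPM (SD, n = 3 each; 1.22 ± 0.30), and its reads are uncertain because defensin genes are near-identical copies. Pla2g2a, named for an antibacterial phospholipase, had 1.03 ± 0.24. It is annotated as a polymorphic pseudogene, so its RNA need not give a working enzyme. A division of the libraries that mixed the groups, conditioned replicate 1 with unconditioned replicates 2 and 3 against the others, gave a larger Paneth median, 1.27 in size, and 20 DESeq2 calls. Paneth genes varied within groups: alpha-defensins took 1.46%, 3.01% and 3.55% of the counts in conditioned and 1.96%, 0.975% and 0.704% in unconditioned libraries. Within each group the libraries ranked by mean log2 CPM in the same order on the Paneth and the distal gut list, and in the reverse order on the proximal list. All 12 goblet cell genes were higher (median 0.30, camera adjusted p = 0.00025; adjusted p = 0.493 with an estimated correlation). Over all genes 0 passed by edgeR (4 at an unadjusted p under 0.05, 2 by DESeq2) and adjusted over the list alone 2 did, Spink4 (0.93 ± 0.20) and Ccl6 (0.85 ± 0.19). Without conditioned replicate 3 or unconditioned replicate 3 the goblet median was 0.10 and 0.19.

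Epithelial genes known to respond to microbes had a median of 0.21 with 11 of 16 members higher (camera adjusted p = 0.0292; adjusted p = 0.353 with an estimated correlation). Reg3g, a lectin that kills Gram-positive bacteria, stood at 69.9 ± 28.8 against 28.9 ± 7.32 CPM (SD, n = 3 each; 1.28 ± 0.35), and DESeq2 called it. The related Reg3b had 1.87 ± 0.75 with overlapping groups, and 1.07 without conditioned replicate 1, where it stood at 508 CPM. Zg16, a lectin of goblet cells, had 0.39 ± 0.15. By edgeR 0 of these passed over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05). The list missed without conditioned replicate 1, 2 or 3, with medians of 0.06, 0.12 and 0.10, and without unconditioned replicate 3 (median 0.11, tested direction reversed). Without unconditioned replicate 1 its median was 0.31. The filter was run again in each of these fits, so the members behind these medians may differ. Enteroendocrine genes had 14 of 15 members higher (median 0.22, camera adjusted p = 0.00379; adjusted p = 0.45 with an estimated correlation), with Cck, a hormone of fat sensing, at 1.13 ± 0.34 and Neurod1 at 0.57 ± 0.27. They missed without conditioned replicate 3 (0.25) or unconditioned replicate 1 (0.17), and had a median of 0.35 without unconditioned replicate 3. Tuft cell genes had 10 of 11 members lower (median -0.14, camera adjusted p = 0.0227; adjusted p = 0.611 with an estimated correlation), with Gfi1b at -0.99 ± 0.32 and the channel Trpm5 at -0.41 ± 0.15. They missed without conditioned replicate 1 (-0.08) or 2 (-0.17) or unconditioned replicate 1 (0.03), and had -0.28 and -0.23 without conditioned replicate 3 or unconditioned replicate 2. Of the enteroendocrine and tuft genes 0 passed by edgeR over all genes or adjusted over the list alone (1 and 2 at an unadjusted p under 0.05, 0 by DESeq2).

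Genes of antigen presentation and interferon gamma were lower as a list (median -0.39, 18 of 20 lower, camera adjusted p = 3.74e-05; adjusted p = 0.603 with an estimated correlation). Cd74, the chaperone of MHC class II, had -0.65 ± 0.30 and the class II gene H2-Aa -0.72 ± 0.35. Conditioned replicate 3 was lowest, and without it the list missed, with a median of -0.16. The median was -0.72 without conditioned replicate 1 and -0.26 without unconditioned replicate 2. Type I interferon genes were also lower (median -0.33, 21 of 22 lower, camera adjusted p = 0.00585; adjusted p = 0.735 with an estimated correlation), with Oas1g at -0.89 ± 0.39 and Ifi44 at -1.30 ± 0.65. Unconditioned replicate 2 was highest, and without it the list missed, with a median of -0.00. The list also missed without conditioned replicate 2 (-0.26) or 3 (-0.18), and had -0.59 and -0.58 without conditioned replicate 1 or unconditioned replicate 1. Both lists were higher in conditioned replicate 1 and unconditioned replicates 2 and 3 than in the others, a division that crosses the groups. Relative to the mean of the 6 libraries, antigen presentation had mean log2 CPM of 0.29, 0.32 and 0.29 there, against -0.18, -0.78 and 0.04. Type I interferon had 0.20, 0.78 and 0.11 against -0.28, -0.44 and -0.38. No member of either list passed by edgeR (0 of 20 and 0 of 22 over all genes or adjusted over the list alone, 0 at an unadjusted p under 0.05) or by DESeq2 (0).

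Intraepithelial and cytotoxic lymphocyte genes had 14 of 15 members lower (median -0.19, camera adjusted p = 0.0428; adjusted p = 0.792 with an estimated correlation), with Cd160 at -0.32 ± 0.19 and Prf1, the pore-forming perforin, at -0.55 ± 0.35. Its median was -0.54, -0.12 and 0.04 without conditioned replicate 1, 2 or 3, and -0.39, -0.02 and -0.13 without unconditioned replicate 1, 2 or 3. It passed in the fits without conditioned replicate 1 and unconditioned replicate 1. This list too parted across the groups. Its mean log2 CPM was 0.40, 0.39 and 0.27 in conditioned replicate 1 and unconditioned replicates 2 and 3, relative to the mean of the 6 libraries. The others had -0.10, -0.65 and -0.31. Macrophage and dendritic cell genes were higher (median 0.24, 13 of 17 higher, camera adjusted p = 0.00379; adjusted p = 0.541 with an estimated correlation), with Clec9a at 0.47 ± 0.20 and Lyz2 at 0.65 ± 0.30. They missed without unconditioned replicate 1 (0.11). Of these lymphocyte and macrophage genes 0 passed by edgeR over all genes or adjusted over the list alone (0 and 1 at an unadjusted p under 0.05, 0 by DESeq2). The T cell list did not pass (median 0.02, mean 0.03, tested direction lower, camera adjusted p = 0.855), and the sign of its median turned with library sizes alone. Of its genes 0 passed at either adjustment by edgeR (0 at an unadjusted p under 0.05, 0 by DESeq2). Without conditioned replicate 3 it passed as higher (0.20, camera adjusted p = 0.0106). Cd2 had 1.01 ± 0.60 and Cd28 0.44 ± 0.28. Granulocyte and mast cell genes did not pass (median -0.12, mean -0.88, camera adjusted p = 0.669). Adjusted over the list alone, 2 members passed in opposite directions, the neutrophil gene Retnlg (1.12 ± 0.35) and the mast cell protease Cpa3 (-2.17 ± 0.65), and 0 over all genes by edgeR (6 at an unadjusted p under 0.05, 0 by DESeq2). Unconditioned replicate 1 stood apart in mast cell genes, with Cpa3 at 2.76 CPM against 0.797 and 0.548 CPM in the other unconditioned libraries. The protease Mcpt1 stood at 46.8, 5.60 and 5.85 CPM in unconditioned replicates 1 to 3 and at 1.17, 1.24 and 2.05 CPM in conditioned ones. Mcpt2 stood at 20.4, 2.44 and 2.10 against 0.463, 0.882 and 0.671 CPM. In these 2 proteases the other unconditioned libraries thus also lay above all conditioned ones. Of the list's 8 tested genes, 4 were higher and 4 lower. Without unconditioned replicate 1 Cpa3 had a log2 fold change of -1.15. The innate cytokine and NF-kB list did not pass (camera adjusted p = 0.368), with a median of -0.04, a mean of 0.16 and a higher tested direction. Nfkbia, the inhibitor induced by NF-kB, passed adjusted over the list alone (0.89 ± 0.15), and Ccl28 had 0.30 ± 0.10. Over all genes 0 of the list passed by edgeR (3 at an unadjusted p under 0.05, 1 by DESeq2).

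Immediate early and heat shock genes rose as a list (median 0.48, 14 of 16 higher, camera adjusted p = 1.34e-08; adjusted p = 0.353 with an estimated correlation). Of them 0 passed over all genes by edgeR (7 at an unadjusted p under 0.05, 5 by DESeq2), and 5 adjusted over the list alone: Fos, Jun, Ier2, Zfp36 and the phosphatase Dusp1 (1.63 ± 0.23). Without conditioned replicate 3 the median was 0.23. This list marks handling of tissue as well as stimulation. Circadian clock genes had 13 of 17 members higher (median 0.19, camera adjusted p = 0.0426; adjusted p = 0.576 with an estimated correlation). Of them 1 passed over all genes and 1 adjusted over the list alone, Per1 both times, and Cry2, another repressor of the clock, had 0.43 ± 0.14. The clock list missed without conditioned replicate 1 (0.32), 2 (0.14) or 3 (0.06) or unconditioned replicate 1 (0.05) or 2 (0.05), and had 0.52 without unconditioned replicate 3.

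Lists of lipid absorption (median 0.10, camera adjusted p = 0.2; Apoa1 0.31 ± 0.12, Npc1l1 0.30 ± 0.15) and of carbohydrate and protein digestion (median 0.08, camera adjusted p = 0.271; Slc5a1 0.31 ± 0.17, Slc2a2 0.31 ± 0.17) did not pass, and their signs turned with library sizes alone. Lipid absorption passed without conditioned replicate 3 (0.18, camera adjusted p = 0.029) or unconditioned replicate 3 (0.16, 0.0201). Fatty acid oxidation genes did not pass (median -0.10, camera adjusted p = 0.142), with Cpt1a at -0.30 ± 0.08, but passed without conditioned replicate 1 (-0.29, camera adjusted p = 0.00407) or unconditioned replicate 1 (-0.18, 0.00348). Cholesterol synthesis genes did not pass (median -0.04, mean 7e-04, tested direction lower, camera adjusted p = 0.512), with Stard4 at -0.22 ± 0.10, but passed as higher without conditioned replicate 1 (0.11, camera adjusted p = 0.0118) and as lower without conditioned replicate 2 (-0.15, 0.0491). Xenobiotic metabolism genes did not pass (median -0.08, mean 0.06, tested direction lower, camera adjusted p = 0.837), with Cyp1a1, a target of the aryl hydrocarbon receptor, at 2.52 ± 0.58 and the esterase Ces2a at -0.49 ± 0.13, but passed as lower without unconditioned replicate 1 (-0.20, camera adjusted p = 0.00768). The unfolded protein response did not pass (median -0.07, camera adjusted p = 0.512). Its member Herpud1 passed adjusted over the list alone (0.91 ± 0.13) and the chaperone Hyou1 had -0.35 ± 0.12. Cell cycle and stem cell genes were lower (median -0.15, 14 of 18 lower, camera adjusted p = 0.02; adjusted p = 0.735 with an estimated correlation), with Mcm6 at -0.59 ± 0.16 and Mki67 at -0.27 ± 0.15. They missed without conditioned replicate 1 (-0.01) or unconditioned replicate 3 (-0.09), and had -0.25 without conditioned replicate 3. Over all genes 0 members of these metabolism, stress and cell cycle lists passed by edgeR (at most 4 per list at an unadjusted p under 0.05, at most 1 by DESeq2), and Herpud1 was the 1 gene that passed adjusted over the list alone.

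Markers of other tissues differed between libraries. Fat tissue genes had 9 of 9 members higher (median 1.75, camera adjusted p = 0.0368; adjusted p = 0.681 with an estimated correlation), and Adipoq stood at 18.3 CPM in conditioned replicate 2 against 0.235 to 4.87 CPM in the others. Without that library the median was -0.11. The fat list also missed without conditioned replicate 1 (1.78) or unconditioned replicate 1 (1.20) or 2 (1.19). Its members with the smallest p were Cidec (0.51 ± 0.17) and Pnpla2 (0.30 ± 0.11), which enterocytes also express. Blood genes were higher (median 0.66, 4 of 6 higher, camera adjusted p = 0.00379; adjusted p = 0.493 with an estimated correlation), missing without conditioned replicate 1 (0.61). Their 4 globin genes passed adjusted over the list alone, with Hba-a2 at 1.15 ± 0.28 and Hbb-bt at 0.71 ± 0.21. Pancreas genes did not pass (median 0.58, camera adjusted p = 0.113; Clps 1.12 ± 0.32, Pnliprp1 0.72 ± 0.30). Within each group Clps and Pnliprp1 ranked the libraries in the same order as the Paneth list, and the source of their reads was not tested. Over all genes 0 of these fat, blood and pancreas genes passed by edgeR (2, 4 and 2 at an unadjusted p under 0.05, 0, 0 and 1 by DESeq2), and the globin genes alone passed adjusted over the list alone.

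Smooth muscle (median -0.08, camera adjusted p = 0.747; Mylk -0.14 ± 0.15, Tagln -0.15 ± 0.19) did not pass. Nor did fibroblast and endothelium (0.09, camera adjusted p = 0.212; Dcn 0.34 ± 0.22, Col1a2 0.13 ± 0.10) or enteric neuron and glia (median 0.05, mean -0.06, tested direction lower, camera adjusted p = 0.952; Elavl4 -0.46 ± 0.23, Vip 0.34 ± 0.22), whose signs turned with library sizes alone. Smooth muscle passed as higher without unconditioned replicate 1 (0.22, camera adjusted p = 0.00396), and fibroblast and endothelium without unconditioned replicate 2 (0.19, 0.0383). Lists of gut position did not pass, and the signs of their medians turned with library sizes alone too. The distal list had a median of 0.08, a mean of -0.44 and a higher tested direction (camera adjusted p = 0.855), with Nr0b2 and Amn (0.53 ± 0.16) passing adjusted over the list alone. The proximal list had a median of 0.06 (camera adjusted p = 0.855), with Tfrc passing adjusted over the list alone and Cybrd1 at 0.40 ± 0.31. Over all genes 0 members of these lists passed by edgeR (2 distal and 1 proximal gene at an unadjusted p under 0.05, 1 each by DESeq2), and 0 of the muscle, stromal and nerve genes did so at either adjustment (0 at an unadjusted p under 0.05, 0 by DESeq2). Of the sex-linked genes 1 was tested, Xist (-0.23 ± 0.13), which was expressed in all 6 libraries.

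Ribosomal protein genes rose as a list (median 0.28, 75 of 78 higher, camera adjusted p = 4.57e-18; adjusted p = 0.493 with an estimated correlation). Of them 0 passed over all genes by edgeR (35 at an unadjusted p under 0.05, 9 by DESeq2) and 9 adjusted over the list alone, including Rps29 (0.91 ± 0.17) and Rpl35 (0.72 ± 0.15), whose reads are uncertain because of processed pseudogenes. Without conditioned replicate 2 the median was 0.17. Replication-dependent histone genes, most of whose transcripts lack a poly(A) tail, rose as a list (median 0.71, 50 of 53 higher, camera adjusted p = 1.6e-17; adjusted p = 0.353 with an estimated correlation). Of them 0 passed over all genes by edgeR (25 at an unadjusted p under 0.05, 10 by DESeq2) and 8 adjusted over the list alone, including Hist1h3a (1.48 ± 0.21) and Hist1h3f (1.06 ± 0.17), which are close copies. Without conditioned replicate 3 the median was 0.45. Genes of the mitochondrial genome had 12 of 12 members higher (median 0.16, camera adjusted p = 0.0165; adjusted p = 0.45 with an estimated correlation), with mt-Nd6 at 0.50 ± 0.19 and mt-Cytb at 0.19 ± 0.11. They missed without conditioned replicate 1 (0.15) or 2 (0.15) or unconditioned replicate 2 (0.15), and 0 members passed by edgeR at either adjustment (1 at an unadjusted p under 0.05, 0 by DESeq2).

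**Figure D3:**
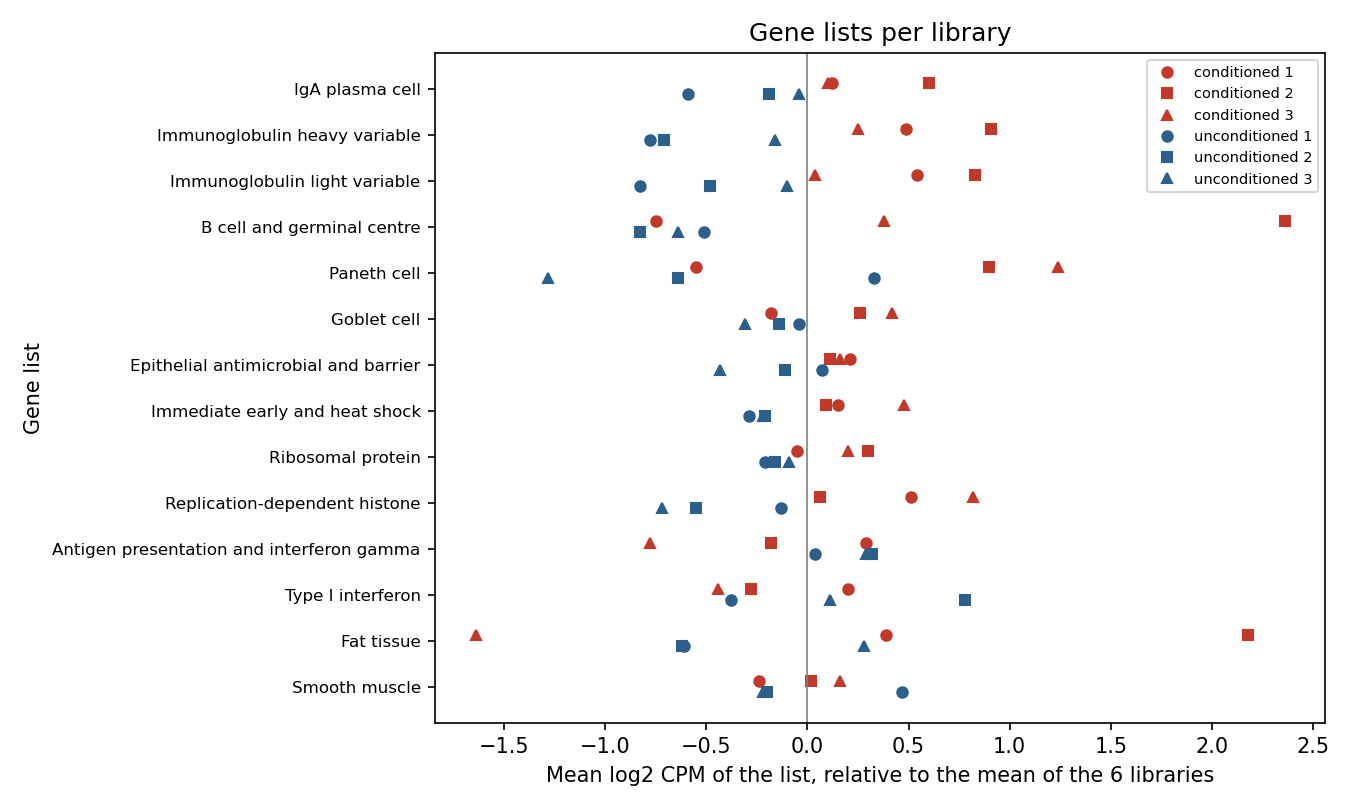
Mean log2 CPM of 14 gene lists per library, relative to the mean of the 6 libraries; red symbols are conditioned and blue symbols unconditioned libraries. The IgA plasma cell list lies between 0.10 and 0.60 in conditioned and between -0.59 and -0.04 in unconditioned libraries, while the B cell and fat tissue lists stand apart in conditioned replicate 2, at 2.36 and 2.18.

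In all, 21 of 36 tested lists passed by camera, 16 higher and 5 lower, and 0 passed with an estimated correlation or by fry (3 and 4 at an unadjusted p under 0.05). With library sizes alone, which moved the median of all genes from -0.01 to -0.12, 17 lists were higher and 2 lower. The medians whose signs turned with library sizes alone moved with this shift of all genes, so that their turn is not a change relative to other genes. In every fit that left out a library, 9 of the 21 lists passed, and the other 12 missed in at least 1.

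The groups overlapped on each of the first 2 principal components alone and parted on both together. With only 6 libraries some other groupings part on 2 components too, so this is no evidence of a group difference. Principal component 1 of log2 CPM held 27.3% of the variance, with conditioned replicates 2 and 3 at 29.79 and 38.33 and conditioned replicate 1 at -12.49, beside the unconditioned libraries at -7.93, -23.59 and -24.12. Principal component 2 held 25% and set conditioned replicates 1 to 3 at 44.06, 12.71 and -10.7, against -32.37, -11.16 and -2.55 for unconditioned replicates 1 to 3. Correlations across genes were 0.980 to 0.989 within groups and 0.979 to 0.984 across them. The chi-square of counts per gene between replicates was at least 21.18, so that no library was a copy of another of its group.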

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

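The offset on transcript length and the DESeq2 fits with a library left out were chosen after the data were seen. The 3 edgeR calls passed again with DESeq2 size factors, upper-quartile scaling, the stricter CPM filter, mitochondrial genome genes left out, a fold minimum of 1.5 and the length offset. With an adjusted p below 0.01, library sizes alone or limma-voom, the count of genes changed was 1, BC035947 each time. Without a filter it was 32 among 31407 genes (30 higher, 2 lower), and by DESeq2 169. With the replicate number as a block it was 2, BC035947 and Ighv1-81. No pairing by number was seen: deviations of same-numbered libraries from their group means had r of -0.1, 0.0827 and -0.158 across genes. Differently numbered libraries across groups had r of -0.137 to 0.246. A shared litter, cage or day is not excluded by this. With libraries left out in turn, 1 to 14 genes passed by edgeR, fewest without conditioned replicate 3, unconditioned replicate 2 or 3 and most without conditioned replicate 2. By DESeq2 99 to 453 passed, fewest without unconditioned replicate 2 and most without conditioned replicate 1. The cause was not tested.

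The count of gene lists changed was 0 with an estimated correlation and 0 by fry, where the IgA plasma cell list, with a median of 0.56, had adjusted p-values of 0.353 and 0.27. Over its other alternatives it passed, and its median was 0.37 to 0.68 with libraries left out. Some lists changed direction when a library was left out, as the sign of the test or of the median, and the cause was not tested. Cholesterol synthesis had a median of 0.11 without conditioned replicate 1 (range -0.15 to 0.11). Fat tissue had -0.11 without conditioned replicate 2 (-0.11 to 2.32). Without conditioned replicate 3, T cell genes had 0.20 (-0.12 to 0.20) and intraepithelial lymphocyte genes 0.041 (-0.54 to 0.041). Smooth muscle had 0.22 without unconditioned replicate 1 (-0.21 to 0.22). The antimicrobial list had 0.11, with a lower tested direction, without unconditioned replicate 3 (0.057 to 0.31).

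Of 1412 values of named genes under an alternative, 1353 kept direction and side of the threshold, 16 no longer passed, 43 newly passed and 0 called values reversed. The first count holds 4 uncalled values that changed sign. Of 662 list values, 567 kept both, 79 no longer passed, 10 newly passed and 6 reversed. The 567 hold 32 that passed in neither fit and changed direction.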

Other observations

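The tests of the edgeR count over other splits, of cycling cells and of Mogat1 reads were chosen after their results were seen. The splits of the 6 samples into 3 and 3, 10 with the real one, are too few for a share under 0.05. By edgeR the real split gave 3 genes and the highest other 2, so that 1 split, the real one, gave as many. By DESeq2 it gave 169 and the highest other 272, with 2 splits giving as many. By camera it gave 21 lists and the highest other 27, with 3 splits giving as many. The median of the IgA plasma cell list was 0.56 and the highest other 0.446 in size, with 1 split, the real one, as large. The split with 272 genes set conditioned replicate 1 with unconditioned replicates 2 and 3, and it held 20 Paneth cell genes (4 in the real split) with a Paneth list median of 1.27 in size (1.17 in the real split), which points to a structure of the samples along Paneth cell genes that crosses the groups. The gut position lists parted the same way: the proximal list had mean log2 CPM of 0.33, 0.16 and 0.24 in those libraries, relative to the mean of the 6, and 0.09, -0.35 and -0.47 in the others, and the distal list -0.48, -0.20 and -0.42 against -0.03, 0.28 and 0.85. The antigen presentation, type I interferon and intraepithelial lymphocyte lists parted there too, each higher in conditioned replicate 1 and unconditioned replicates 2 and 3.

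Histone genes were higher as a list by camera (adjusted p = 1.6e-17; adjusted p = 0.353 with an estimated correlation), with a median log2 fold change of 0.74 in the 51 members with a known length. Transcript length as the whole cause is argued against, since that median lay at percentile 100 of 10000 lists matched on length and expression. The central 95% of those lists had medians of 0.000265 to 0.15. They hold unrelated genes, while histone genes may move together from library to library, so that percentile may overstate the evidence. Conditioned replicates 1 and 3 with unconditioned replicate 1 gave the highest histone median of the other splits, 0.477 in size. That split had 6 histone calls by DESeq2, against 10 in the real one. More cycling cells were not seen in the cell cycle list, whose median was -0.146 (95% bootstrap interval over genes -0.221 to -0.0313). They are not excluded, because the libraries overlapped on this list. Its mean log2 CPM was -0.35, -0.01 and 0.14 in conditioned and 0.03, 0 and 0.19 in unconditioned libraries, relative to the mean of the 6. Without conditioned replicate 1 the median was -0.007. A difference in how well RNAs without a poly(A) tail were captured stays open and may explain part of this: 55 other such RNAs had a median of 0.428 (95% interval 0.218 to 0.73), 40 of them higher. That interval is over genes, and the libraries overlapped, with mean log2 CPM of 0.78, -0.34 and 0.31 in conditioned and 0.13, -0.72 and -0.15 in unconditioned libraries, relative to the mean of the 6. A response of histone genes to conditioning stays open too and was not tested apart.

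Per1 rose, and the immediate early and heat shock list was higher by camera (adjusted p = 1.34e-08; adjusted p = 0.353 with an estimated correlation) but not by fry (adjusted p = 0.219), with 0 of its 16 members past edgeR's threshold over all genes (7 at an unadjusted p under 0.05, 5 by DESeq2). A change as large as that of Per1 (0.84) was not typical of 9 other clock genes, with a median absolute log2 fold change of 0.195 (95% interval 0.03 to 0.307). This cannot exclude a smaller shift of the clock phase. Per1 was the clock gene that passed, the interval is over genes, and the 9 leave out Cry2 (0.43 ± 0.14) and other list members. Heat shock on handling cannot be told apart: 6 heat shock genes had a median of 0.248 (95% interval 0.0247 to 0.439), close to the bound of 0.258 set by the immediate early genes. Glucocorticoid signalling may be a source. The list of targets was drawn up after the data were seen. Of 32 targets tested, DESeq2 called 14, of which 0 were lower, but these include Per1 and Dusp1, the genes to be explained. In 16 of the targets that DESeq2 did not call, which leaves out the uncalled Pdk4 (0.88) and Angptl4 (1.33), the median was 0.485, with 14 higher, at percentile 100 of 10000 lists matched on expression, of which the central 95% had medians of -0.0855 to 0.103, and the highest other split of the samples gave 0.294. The matched lists hold unrelated genes, while targets of a pathway may move together from library to library, so that percentile may overstate the evidence. Whether such a signal came from conditioning or from stress at sampling stays open.

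BC035947 was on in conditioned and nearly off in unconditioned libraries. Mogat1, which overlaps it, also separated the groups, with 7 to 17 counts per conditioned and 0 to 2 per unconditioned library (ratio 16.5, 95% counting interval 4.21 to 142). The test as first written asked only for that separation and was met. A bound that Mogat1 should reach 50 percent of the BC035947 count was added after those counts were seen, because 1358 exon bases of Mogat1 lie outside BC035947, and Mogat1 reached at most 6.34%, which argues against its reads as the whole cause. Inherited variants between litters or substrains cannot be told apart, since 0 other genes had at least 30 counts in every library of one group and at most 3 in every library of the other, which leaves a single locus possible, and conditioning itself stays open as well.

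Some libraries stood apart in genes of other cells. Conditioned replicate 2 had 18.3 CPM of Adipoq. Unconditioned replicate 1 had 39.3 CPM of Fabp6, an ileal bile acid carrier, against 0.109 to 1.54 CPM in the other libraries, while Slc10a2, an ileal bile acid transporter, was highest in conditioned replicate 3, at 16.3 CPM against 9.64 CPM in unconditioned replicate 1.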
